A study of Homo sapiens with 31 samples.

How the data were processed

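MDA-MB-231 breast cancer cells and normal human mammary epithelial cells (HMEC), each with an inducible shRNA against EIF4E or a non-silencing shRNA, were grown with doxycycline for 6 days per the labels' protocols. RNA was measured in total RNA and in polysomes of 2 to 3 (light), 4 to 6 (moderate) and more than 6 ribosomes (heavy). There were 31 libraries from 8 cultures, 16 of MDA-MB-231 and 15 of HMEC. The total RNA of HMEC shEIF4E replicate 2 was not analysed here.

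The authors deposited raw counts per gene symbol for the 31 libraries in 1 table, with no scaling. The submitters' processing notes name STAR 2.5.0c, limma and the hg19 build without saying what each was used for. The gene annotation, the counting tool, the strand setting and the treatment of reads with several matches are not stated. Counts of genes with close copies, such as ribosomal protein, histone and MAGE genes, and of genes that overlap another on the opposite strand are therefore uncertain. The values were checked to be whole numbers. Total counts per library ran from 12908527 to 33249118 with a median of 24669875.

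Of 58434 symbols listed, 4 entries of 2 duplicated date-like symbols were dropped, which held at most 0.00652% of any library, and 23 other date-like symbols were kept under the name given. The table held 0 genes of mitochondrial DNA, so the list of 13 such genes could not be tested. Gene features came from GENCODE 29 on GRCh38, joined by symbol, and 34442 symbols matched. Since that build differs from the authors', only lengths and GC content were taken from it, and symbols renamed between both annotations were lost to the length checks.

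Groups followed the titles and labels. The titles of 2 MDA-MB-231 control libraries contradict themselves: the code of each says light and the words moderate, or the reverse. The library coded light correlated at 0.993 with the light library of replicate 1 and at 0.955 with the moderate one, and the library coded moderate at 0.973 and 0.992. The light and moderate counts of each culture were summed in every culture, which makes the sum independent of that question and left 23 libraries in 12 groups of cell line, shRNA and RNA class. Counts were added without scaling, so light and moderate RNA weigh in the sum by sequencing depth and not by amount of RNA.

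Genes were kept with filterByExpr (minimum count 10), which left 18853. All libraries were scaled with TMM and fitted together in edgeR 4.0.16 (R 4.3.3) with 1 mean per group and 11 residual degrees of freedom, and comparisons were made with the quasi-likelihood F test. These degrees of freedom count the RNA classes of a culture as separate, although their deviations were correlated, as given below. Fewer of them measure spread between cultures. If nothing changed and p-values were exact, a share of about 0.05 of the tested genes would have an unadjusted p under 0.05. All interaction terms but HMEC heavy minus total stayed below that share. Their tests were thus conservative, and a count of 0 does not show that nothing changed. The common biological coefficient of variation was 0.183. Fitted alone it was 0.116 in MDA-MB-231 (16154 genes) and 0.249 in HMEC (16658 genes). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Standard errors of log2 fold changes were derived from the F statistic. The lone HMEC shEIF4E total RNA library was assumed to vary like the other groups. Comparisons were shEIF4E minus control in each cell line and RNA class, the same for heavy minus total and heavy minus light plus moderate (interaction terms), the difference of these changes between cell lines, and heavy minus light plus moderate in control cells.

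Lists of 28 gene groups were fixed before the data were examined, and 27 with at least 5 tested members were tested. They covered cap binding and initiation, transcripts described as sensitive to eIF4E, cytosolic and mitochondrial ribosomal proteins, other TOP genes, oxidative phosphorylation, the integrated stress, unfolded protein, heat shock, antioxidant and interferon responses, NF-kB, p53, immediate early genes, DNA replication, mitosis, histones, cholesterol, glycolysis, lysosomes, nuclear-retained RNA, reference genes and markers of basal, luminal, mesenchymal, stromal and immune or endothelial cells. The plan named the 5 marker lists, the mesenchymal list among them, for use only as levels per library. Its entry on list tests covered every list, and all 5 were tested. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and again with an estimated correlation, and with fry, adjusted over lists within a comparison. Results for lists are from camera unless fry is named. Members were also adjusted over their list alone.

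The genes named were up to 6 higher and 6 lower per comparison with the largest log2 fold change. They had to be called, to have a mean log2 CPM of at least 4 over the libraries compared, not to overlap between groups and not to have a clone name. EIF4E and 6 relatives or partners, and up to 4 members with the smallest p from each list described, were named in addition. A gene selected by this rule for the difference between cell lines in heavy polysomes is not reported here. Checks across genes used 8107 genes with a mean log2 CPM of at least 4, and 7867 of these (97%) had a coding length.

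RNA classes prepared from the same culture were treated as paired in 1 alternative, since they came from the same cells. Deviations from the group mean correlated between RNA classes of a culture at 0.12 to 0.75 in MDA-MB-231 and 0.57 to 0.79 in HMEC across 8107 genes. Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, no filter on low counts, a block for the replicate number, a block for the culture, a separate fit for each cell line, light or moderate libraries alone under each reading of the contradicting titles, and leaving out each library in turn (22 fits). A separate fit together with the culture block was added after the data were seen. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

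The tests were tried on simulated data with the depth of these libraries. The changed genes, 66 or 67 for each fold, were drawn only from genes above a floor on mean level. The shares called thus do not cover genes with fewer counts. Each gene had a mean level and a spread shared by both cell lines, and RNA classes of a culture were drawn independently. The coefficient of variation fitted alone was 0.249 in HMEC and 0.116 in MDA-MB-231. The shares called may thus be too high for HMEC and too low for MDA-MB-231, and false calls too few for HMEC. In MDA-MB-231 total RNA, 10.4% of genes changed 1.5-fold, 58.2% of those changed 2-fold and 98.5% of those changed 4-fold were called. The values were 7.5%, 31.3% and 89.4% in HMEC total RNA, 11.9%, 56.7% and 97% in HMEC heavy polysomes, 1.5%, 19.4% and 90.9% for heavy minus total in MDA-MB-231, and 0%, 14.9% and 83.3% for the difference between cell lines in heavy polysomes. False calls made up 0% to 7.6% of calls.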

Results

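RNA was sequenced from MDA-MB-231, a breast cancer cell line, and from HMEC, normal human mammary epithelial cells. Cells of each kind carried a doxycycline-inducible short hairpin RNA, either against EIF4E (shEIF4E) or a non-silencing control, and had been induced for 6 days. EIF4E encodes the protein that binds the cap of mRNA and recruits it to the ribosome. For each culture, total RNA and RNA from polysomes of 2 to 3 ribosomes (light), 4 to 6 ribosomes (moderate) and more than 6 ribosomes (heavy) were measured. The 31 libraries came from 8 cultures, 2 per cell line and shRNA, with 16 libraries for MDA-MB-231 and 15 for HMEC. Each group held 2 libraries, except that 1 total RNA library of HMEC shEIF4E was analysed. The light and moderate libraries of a culture were summed, which left 23 libraries in 12 groups. Total counts per library ran from 20708054 to 29524714 in MDA-MB-231 and from 12908527 to 33249118 in HMEC, with a median of 24669875 over both.

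Libraries separated first by cell line, along a component with 69.8% of the variance, and then by heavy against lighter polysomes, along a component with 11.4%. Across genes, replicate libraries correlated at 0.992 to 0.995 in MDA-MB-231 and at 0.973 to 0.983 in HMEC, where genes are not independent replicates. The basal keratin KRT5 stood at 120 to 2970 counts-per-million (CPM) in the HMEC libraries and at no more than 0.206 CPM in those of MDA-MB-231. Within HMEC, the control cultures differed in these markers. KRT5 in heavy polysomes stood at 1560 CPM in control replicate 1 and 753 CPM in control replicate 2, against 2910 and 2970 CPM in the shEIF4E cultures, and the adhesion gene CDH1 at 17.5 and 4.62 CPM against 55 and 27.9 CPM. VIM, which encodes the intermediate filament vimentin, stood at 3430 and 5840 CPM against 7290 and 5040 CPM. Each shRNA in each cell line was represented by 1 stable line, so no p-value measures spread between such lines. The p-values rest on a spread pooled over both cell lines, with the RNA classes of a culture counted as separate. They may be too small for HMEC, whose coefficient of variation fitted alone was 0.249, against 0.116 in MDA-MB-231.

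EIF4E itself was lower with shEIF4E in every library. In MDA-MB-231, its mean level in total RNA was 54.3 ± 0.631 CPM (SD, n = 2) in control cells and 15.1 ± 2.88 CPM (n = 2) with shEIF4E. In heavy polysomes it was 22.1 ± 0.882 against 6.36 ± 1.55 CPM, and in light plus moderate polysomes 67.7 ± 6.85 against 16.6 ± 2.39 CPM (n = 2 each). In HMEC, total RNA held 39.1 ± 0.463 CPM in control cells (n = 2) and 7.97 CPM in the single shEIF4E library. Heavy polysomes of HMEC held 28.9 ± 2.24 against 3.31 ± 0.595 CPM and light plus moderate polysomes 57.8 ± 6.72 against 6.07 ± 0.593 CPM (n = 2 each). On the log2 scale the change of EIF4E was -1.85 ± 0.18 (SE) in MDA-MB-231 total RNA, -1.80 ± 0.19 in heavy and -2.03 ± 0.18 in light plus moderate polysomes. In HMEC it was -2.29 ± 0.25, -3.12 ± 0.21 and -3.25 ± 0.19 in the same order. The adjusted p by edgeR's quasi-likelihood test lay between 7.25e-08 and 0.00096. In a fit of the HMEC libraries alone, the total RNA value was -2.33 with an adjusted p of 0.0612. Of its relatives and partners, EIF4E2, EIF4E3, EIF4EBP1, EIF4G1 and EIF4A1 passed the test in no comparison of both shRNAs. This does not show that they were unchanged: in MDA-MB-231 EIF4E3 lay at -0.833 ± 0.422 in total RNA, -0.786 ± 0.440 in heavy and -1.003 ± 0.410 in light plus moderate polysomes (adjusted p 0.109 to 0.288). EIF4EBP2, which encodes a repressor of eIF4E, passed only in light plus moderate polysomes of HMEC, where it fell by 0.70 ± 0.17 (adjusted p 0.0389, n = 2 against 2).

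**Figure D1:**
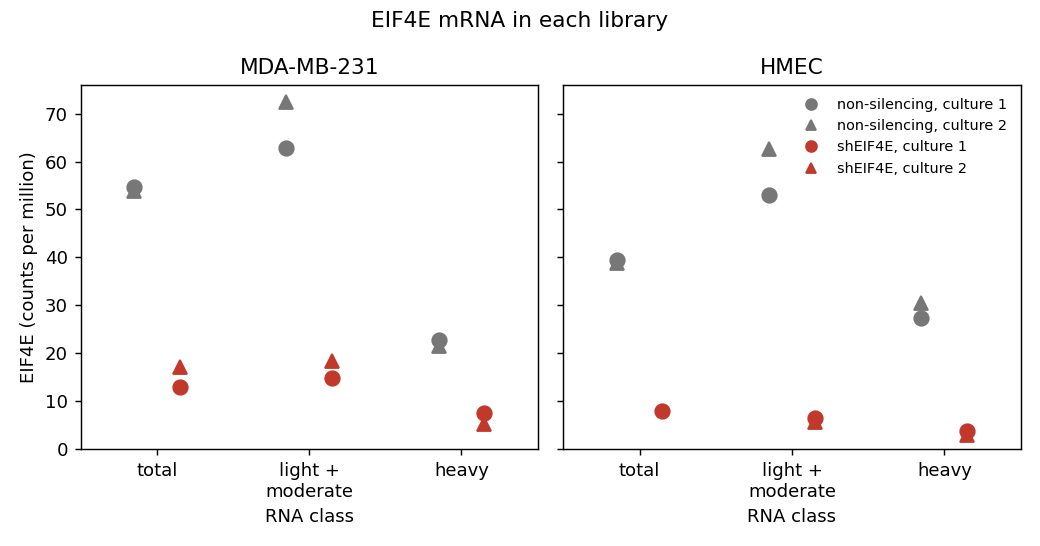
EIF4E level in CPM in each library, by cell line, RNA class and shRNA, with 1 point per library and a shape for each culture. Every shEIF4E library lay below the control libraries of its class, for example at 7.46 and 5.26 against 22.8 and 21.5 CPM in heavy polysomes of MDA-MB-231.

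The total RNA of MDA-MB-231 was compared to ask which transcripts differed in abundance between transformed cells with shEIF4E and with the control shRNA. An effect of silencing and a difference between their stable lines cannot be told apart here. L1CAM, a neural cell adhesion molecule, rose by 4.05 ± 0.36 (log2, SE, n = 2 against 2), LY6E, a surface protein, by 2.64 ± 0.21, and HTRA1, a secreted protease, by 2.63 ± 0.34. APCDD1L, SORCS2 and the long non-coding RNA UCA1 were the other genes of the 6 with the largest increase, at 2.70 to 3.40. SRGN, the proteoglycan of secretory granules, was lower, at -3.98 ± 0.18, as were ESAM, an adhesion molecule of endothelium, at -3.74 ± 0.30, and MXRA8 at -2.97 ± 0.37. ARHGDIB, LPXN and GPSM3 lay at -2.56 to -2.70. In all, 1256 genes were higher and 1196 lower among 18853 tested (adjusted p under 0.05), and of these 508 and 826 changed at least 2-fold. With no floor on level, 278 of the called genes changed at least 16-fold. Leaving out any 1 of the 4 libraries gave 1117 to 1211 calls, and a fit of the MDA-MB-231 libraries alone gave 5097. The share of higher genes, 51.2%, was 57.8% in that fit and turned to 45.9% without control replicate 1, 46.6% without control replicate 2, 47.7% with the RLE scaling and 49.2% without a filter on low counts, and DESeq2 gave 1436 higher and 1437 lower.

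Among the gene lists fixed beforehand, 7 stood apart from other genes in that comparison by camera with its preset correlation. Of 80 cytosolic ribosomal protein genes, 11 were called higher and 0 lower, with 14 adjusted over the list alone (adjusted p = 2.45e-05). RPL7A rose by 0.91 ± 0.12 and RPLP0 by 0.67 ± 0.14. Of 23 other genes with a terminal oligopyrimidine tract (TOP genes), 5 rose, with 7 adjusted over the list alone (adjusted p = 0.00634), among them NAP1L1 by 0.77 ± 0.18. Of 77 nuclear genes for oxidative phosphorylation, 12 rose, also 12 adjusted over the list alone (adjusted p = 0.00634), with CYC1 up by 0.81 ± 0.17 and SDHD by 0.53 ± 0.12. Of 41 genes of mitosis, 9 rose, and 9 adjusted over the list alone (adjusted p = 0.00025), including CCNA2, cyclin A2, by 1.03 ± 0.15 and the kinesin gene CENPE by 0.87 ± 0.15. Of 29 antioxidant genes controlled by NRF2, 9 rose, and 9 adjusted over the list alone (adjusted p = 0.00156). TXNRD1, thioredoxin reductase, rose by 1.51 ± 0.21 and NQO1, a quinone reductase, by 1.41 ± 0.21. Of 24 histone genes, 6 fell, with 8 adjusted over the list alone (adjusted p = 0.00634), HIST1H4H at -1.92 ± 0.37. Of 43 interferon response genes, 9 fell, with 12 adjusted over the list alone (adjusted p = 0.00654), SAMD9L at -1.92 ± 0.32. None of the 7 calls held when camera estimated the correlation between genes: adjusted p = 0.78 with an estimated correlation for the interferon list and adjusted p = 0.603 for each of the others.

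The remaining lists did not pass that test in MDA-MB-231 total RNA. Of 29 transcripts described in the literature as sensitive to eIF4E, HPSE, which encodes heparanase, rose by 2.20 ± 0.36, CD44, a hyaluronan receptor, by 0.79 ± 0.19 and TLK1 by 0.62 ± 0.14. SNAI1, a repressor of epithelial genes, rose from 1.72 ± 0.108 to 4.10 ± 1.42 CPM (SD, n = 2 each, adjusted p 0.00892) but did not pass with limma-voom. None of the 29 was called lower, although 9 had a change below 0 and 19 above, and 4 were called adjusted over the list alone (camera adjusted p = 0.16). By fry, which tests a list without reference to other genes, the list was higher (adjusted p = 0.00969). Fry also passed the lists called by camera (adjusted p = 0.00969 to 0.0429), except the interferon response (adjusted p = 0.249 by fry). Of 49 cap-binding and initiation genes, EIF3E rose by 0.69 ± 0.17, while PDCD4, an inhibitor of the helicase eIF4A, fell by 1.37 ± 0.21 and MKNK2, a kinase of eIF4E, fell by 0.69 ± 0.19, beside EIF4E itself. The same 1 and 3 were called adjusted over the list alone (adjusted p = 0.915). Mesenchymal genes went both ways: 6 of 30 rose, among them TGFBI by 1.85 ± 0.21 and THBS1 by 1.70 ± 0.35, and 4 fell, among them CDH2, N-cadherin, at -1.66 ± 0.32 and ITGA5 at -1.03 ± 0.20. Adjusted over the list alone, 7 rose and 4 fell (adjusted p = 0.263). Of 21 immediate early genes, 4 fell, and 5 adjusted over the list alone, DUSP5 at -1.08 ± 0.15 (adjusted p = 0.16).

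Other lists had few called members in MDA-MB-231 total RNA. For the integrated stress response, 2 of 37 genes rose and 5 fell (adjusted p = 0.663). For the unfolded protein response, 3 of 24 rose and 1 fell, or 3 and 2 adjusted over the list alone (adjusted p = 0.911). Mitochondrial ribosomal proteins had 6 of 76 genes higher, or 4 adjusted over the list alone (adjusted p = 0.288), and genes of DNA replication 5 of 47 higher and 1 lower (adjusted p = 0.201). Targets of p53 had 2 of 26 lower (adjusted p = 0.263), inflammatory genes of NF-kB 2 of 23 lower (adjusted p = 0.288) and glycolysis 1 of 34 lower, HK2 (adjusted p = 0.774). Cholesterol synthesis had 0 of 25 genes called by edgeR, DESeq2 and limma-voom, and 1 at an unadjusted p under 0.05 by edgeR (adjusted p = 0.663). Lysosomal genes had 3 of 26 higher (adjusted p = 0.333), heat shock 1 of 16, HSPE1 (adjusted p = 0.494), and reference genes 1 of 14, SDHA (adjusted p = 0.299). Nuclear-retained RNA had 0 of 9 called by any of the 3 tools, and 0 at an unadjusted p under 0.05 by edgeR (adjusted p = 0.915). Among marker lists, basal genes had 2 of 30 higher and 2 lower (adjusted p = 0.888), luminal genes 3 of 12 lower (adjusted p = 0.0671) and immune or endothelial genes 2 of 6 lower (adjusted p = 0.288). Stromal genes had 3 of 15 higher and 1 lower, or 4 and 1 adjusted over the list alone (adjusted p = 0.263). Where no second count is given, the count adjusted over the list alone was the same.

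In heavy polysomes of MDA-MB-231, the same cultures were compared to ask which mRNAs changed among those carried by more than 6 ribosomes. L1CAM rose by 3.99 ± 0.35 (log2, SE, n = 2 against 2), C3, the complement component, by 2.97 ± 0.20, CLU, the chaperone clusterin, by 2.94 ± 0.56 and DOCK2, a guanine nucleotide exchange factor, by 2.64 ± 0.20. Lower genes were SRGN at -3.92 ± 0.18, the chemokine receptor gene CXCR4 at -3.75 ± 0.46, NTN4, a netrin, at -2.88 ± 0.20 and DUSP1, a MAP kinase phosphatase, at -2.59 ± 0.48. CXCR4 stood at 79.1 ± 12.3 CPM in control cells and 5.87 ± 1.21 CPM with shEIF4E (SD, n = 2 each). Changes of at least 16-fold, with no floor on level, were called for 238 genes of MDA-MB-231, against 20 in heavy polysomes of HMEC. Altogether 1236 genes were higher and 1124 lower in MDA-MB-231, with 497 and 731 changed at least 2-fold. Of the genes called in total RNA, 980 were also higher and 864 also lower here, and 0 went opposite ways. Independent lists would share 82 and 71, but both RNA classes came from the same 4 cultures, so part of the agreement may come from those. Between cultures of different numbers, the covariance of the heavy change with the total RNA change was 0.99 of that between both total RNA changes. This held with either number taken for total RNA, over 8190 genes. The ratio allows for noise in total RNA and is not a plain regression slope. Leaving out any 1 of the 4 libraries gave 1153 to 1454 calls, and a fit of the MDA-MB-231 libraries alone gave 5096. The share of higher genes, 52.4%, was 62.3% in that fit and turned to 46.6% without control replicate 1 and 45.8% without control replicate 2.

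**Figure D2:**
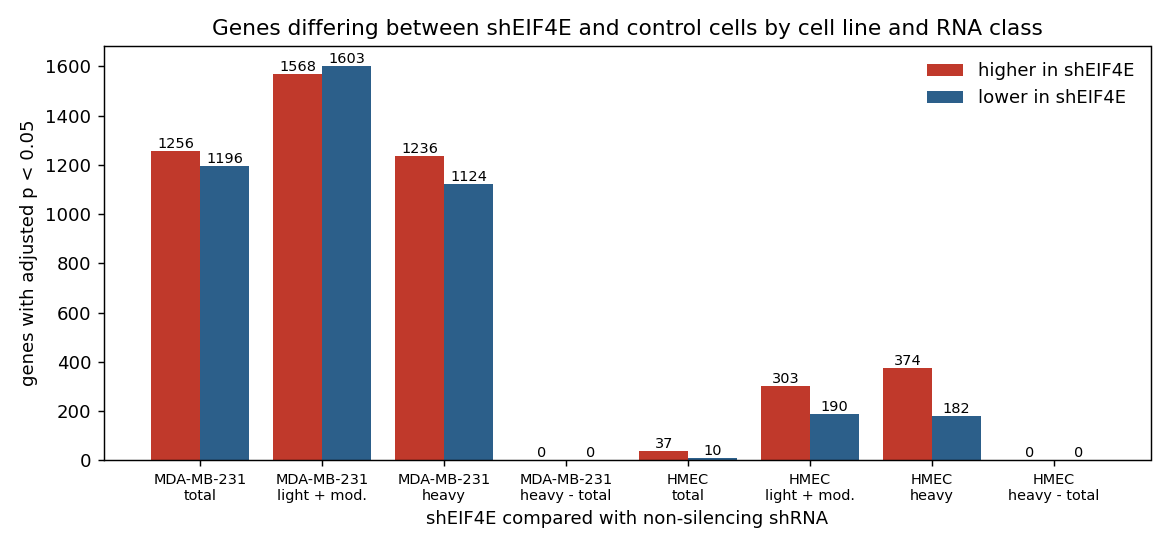
Number of genes called higher and lower with shEIF4E (bars from 0), by cell line, for total RNA, light plus moderate polysomes, heavy polysomes and heavy minus total. MDA-MB-231 had 1236 higher and 1124 lower genes in heavy polysomes against 374 and 182 in HMEC, and heavy minus total had 0 by edgeR's test in each.

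By camera with its preset correlation, 8 lists stood apart in MDA-MB-231 heavy polysomes. Ribosomal protein genes had 12 of 80 higher, or 14 adjusted over the list alone (adjusted p = 0.000384), with RPL7A up by 0.78 ± 0.12 and RPL31 by 1.01 ± 0.19. Oxidative phosphorylation had 11 of 77 higher, or 12 adjusted over the list alone (adjusted p = 0.00086), with SDHD up by 0.67 ± 0.12 and ATP5G3 by 0.79 ± 0.14. Mitosis had 7 of 41 higher, or 9 adjusted over the list alone (adjusted p = 0.000765), with CCNA2 up by 1.05 ± 0.15 and MAD2L1 by 0.86 ± 0.13. Antioxidant genes had 8 of 29 higher, or 9 adjusted over the list alone (adjusted p = 0.00248), with NQO1 up by 1.36 ± 0.21 and SOD1 by 0.70 ± 0.12, and the other TOP genes had 3 of 23 higher, NACA, NAP1L1 and EIF3E, also 3 adjusted over the list alone (adjusted p = 0.027). Interferon response genes had 10 of 43 lower, also 10 adjusted over the list alone (adjusted p = 0.002), with SAMD9L down at -1.93 ± 0.32 and IRF7, a transcription factor, at -1.39 ± 0.28. Immediate early genes had 4 of 21 lower, also 4 adjusted over the list alone (adjusted p = 0.0142), and all of these encode phosphatases of MAP kinases or an apoptosis regulator: DUSP1, DUSP5 at -1.35 ± 0.15, DUSP6 at -0.94 ± 0.23 and IER3. Luminal markers had 3 of 12 lower, or 5 adjusted over the list alone (adjusted p = 0.019), ELF3 at -2.15 ± 0.50 and 2 trefoil genes with few counts. With an estimated correlation none of the 8 held (adjusted p = 0.775 with an estimated correlation for interferon and adjusted p = 0.67 for the others). Of the 29 literature transcripts, HPSE, TLK1, CD44 and SNAI1 rose and CCND3, cyclin D3, fell by 0.52 ± 0.14, with 6 higher and 2 lower adjusted over the list alone (adjusted p = 0.143).

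The light plus moderate polysomes of MDA-MB-231 were compared for the mRNAs on 2 to 6 ribosomes. CCDC3 rose by 4.55 ± 0.29 (log2, SE, n = 2 against 2), STMN3, a stathmin, by 3.48 ± 0.30, HTRA1 by 3.16 ± 0.35 and the cancer-testis gene MAGEA12, whose reads may be shared with close relatives in its family, by 2.96 ± 0.22. SRGN at -3.96 ± 0.18, ESAM at -3.81 ± 0.29 and the cytokine gene IL11 at -2.52 ± 0.50 were lower. In total, 1568 genes were higher and 1603 lower. Mitosis had 17 of 41 genes higher and 0 lower, or 18 adjusted over the list alone (adjusted p = 7.79e-06), and DNA replication 7 of 47 higher and 1 lower, also 7 and 1 adjusted over the list alone (adjusted p = 0.0041). MCM6, part of the replicative helicase, rose by 0.98 ± 0.14 and CHAF1B, a chromatin assembly factor, by 0.86 ± 0.12, while GINS4, another of its parts, fell by 0.94 ± 0.15. Antioxidant genes had 9 of 29 higher, or 10 adjusted over the list alone (adjusted p = 0.00312), and other TOP genes 10 of 23 higher, or 12 higher and 2 lower adjusted over the list alone (adjusted p = 0.00336), with the elongation factor EEF2 up by 0.98 ± 0.19. Histones had 7 of 24 lower, or 8 adjusted over the list alone (adjusted p = 0.00336), HIST1H4H at -2.49 ± 0.35. Oxidative phosphorylation had 12 of 77 higher (adjusted p = 0.0231) and ribosomal proteins 7 of 80, or 5 adjusted over the list alone (adjusted p = 0.0238). None of these 7 calls held with an estimated correlation, with adjusted p = 0.556 to 0.824. Leaving out any 1 of the 4 libraries gave 1377 to 1777 calls, and a fit of the MDA-MB-231 libraries alone gave 5979. The share of higher genes, 49.4%, turned to 51.5% in that fit, 51.1% without shEIF4E replicate 1, 54.9% without shEIF4E replicate 2, 54.1% with DESeq2 and 51.5% with the RLE scaling.

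Heavy minus total in MDA-MB-231 asked whether the level of a transcript in heavy polysomes, relative to other transcripts, changed beyond its abundance. Since levels are relative within each library, a loss of heavy polysomes common to all mRNAs would not show. SRGN, L1CAM and the other genes with the largest changes moved together in both RNA classes, and EIF4E differed by 0.05 ± 0.26 (log2, SE, n = 2 per group). No gene passed: 0 of 18853 by edgeR's quasi-likelihood test, with 134 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma-voom. The same was found with the cultures as a block (0 by edgeR, with 314 at an unadjusted p under 0.05). The 134 and the 314 lie below a share of 0.05 of the tested genes, so the test was conservative. In simulated data with a spread shared by both cell lines, this test recovered 19.4% of 67 genes changed 2-fold and 90.9% of 66 changed 4-fold. The changed genes were drawn from those above a floor on mean level among 17506 tested. Many shifts of 2-fold or less may thus be missed, although the spread fitted in MDA-MB-231 alone was smaller. No fixed list passed by camera. DNA replication genes had the smallest p there, with a median of -0.08 (adjusted p = 0.0772).

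Heavy minus light plus moderate asked whether transcripts shifted along the gradient in MDA-MB-231. No single gene passed: 0 by edgeR, with 255 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma-voom. The 255 lie below a share of 0.05 of the tested genes, so this test was conservative. With the cultures as a block the count was 0 by edgeR, with 1191 at an unadjusted p under 0.05. Of the fixed lists, 5 lay lower than other genes by camera with its preset correlation: DNA replication with a median of -0.21 (adjusted p = 3.23e-08), glycolysis with -0.23 (adjusted p = 0.000396), heat shock with -0.36 (adjusted p = 0.00162), mitosis with -0.13 (adjusted p = 0.0214) and basal markers with -0.23 (adjusted p = 0.0251). Ribosomal protein genes lay higher, with a median of 0.13 (adjusted p = 0.0119). None of the 6 held (adjusted p = 0.854 with an estimated correlation for each). Adjusted over the list alone, 1 gene was lower in the replication list and 1 in the basal list, and 0 in the other 4 by edgeR. Across 7867 genes, which are not independent replicates, this difference went with coding length, with a Spearman correlation of -0.52 for the group means and of -0.38 and -0.56 for the cultures numbered alike. The change had correlations of 0.27 and 0.21 in light plus moderate polysomes and of -0.01 and -0.07 in heavy polysomes. Heavy minus total also fell with coding length, at -0.34 for the group means and -0.19 and -0.32 for the cultures numbered alike. Across 8190 genes, however, its change correlated at -0.01 between the cultures numbered 1 and 2, against 0.5 for heavy minus light plus moderate. The genes with the shortest coding sequences (median 615 nt) changed by 0.19 and 0.13 at the median and those with the longest (3285 nt) by -0.14 in each pair. In HMEC the correlations of heavy minus light plus moderate were 0.12 and -0.13.

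**Figure D3:**
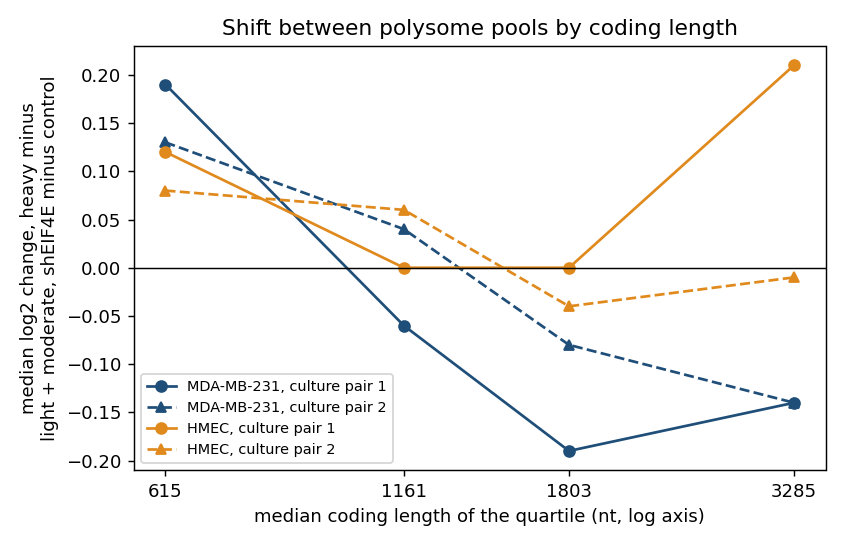
Change of heavy minus light plus moderate polysomes (log2, shEIF4E minus control) by quartile of coding length (median nt), with lines for each pair of cultures with the same replicate number. Both MDA-MB-231 lines lay highest at the shortest quartile, at 0.19 and 0.13, and ended at -0.14, whereas the HMEC lines end at 0.21 and -0.01.

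In HMEC total RNA the same question was put to normal cells, with 1 shEIF4E library whose spread was taken to be that of the other groups. SLIT2, a secreted guidance protein, rose by 2.59 ± 0.36 (log2, SE, n = 1 against 2), F3, tissue factor, by 1.74 ± 0.28, COL1A1, a collagen chain, by 1.74 ± 0.35 and MYH9, non-muscle myosin, by 1.39 ± 0.20. SAMD11 was lower, at -2.60 ± 0.44, and so were GPX3, a secreted glutathione peroxidase, at -1.78 ± 0.33, LRP1, an endocytic receptor, at -1.17 ± 0.23 and SDCBP, syntenin, at -1.11 ± 0.19. These belonged to 37 genes called higher and 10 lower. Without control replicate 1 or 2 the calls were 11 (8 higher and 3 lower) and 1 (lower), and a fit of the HMEC libraries alone gave 0 by edgeR, with 1170 at an unadjusted p under 0.05. DESeq2 gave 411 calls, of which 48.9% were higher against 78.7% here, and testing without a filter on low counts gave 866.

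Single members of the fixed lists seldom passed in HMEC total RNA, but 14 lists stood apart by camera with its preset correlation. Basal markers had a median of 1.12, with 1 of 30 higher, KRT18, a keratin of luminal and other simple epithelium that the luminal list holds too, and 8 adjusted over the list alone (adjusted p = 3.59e-14 and, with an estimated correlation, adjusted p = 0.223). KRT5 in total RNA stood at 664 and 254 CPM in the controls and 1040 CPM with shEIF4E. NF-kB genes had a median of 1.40 and 0 of 23 called, against 16 adjusted over the list alone (adjusted p = 4.39e-13, adjusted p = 0.223 with an estimated correlation). Mesenchymal genes had a median of 0.54 and 0 of 30 called, against 10 higher and 2 lower adjusted over the list alone (adjusted p = 4.47e-07), and this list held (adjusted p = 0.0199 with an estimated correlation). Ribosomal proteins had a median of 0.37 and 0 of 80 called in either count (adjusted p = 1.26e-13, adjusted p = 0.235 with an estimated correlation). At an unadjusted p under 0.05 by edgeR, 16 NF-kB, 15 mesenchymal and 34 ribosomal protein genes passed. DESeq2 called 4, 9 and 3 of them and limma-voom 0 of each. The other 10 were TOP genes (median 0.30), mitochondrial ribosomal proteins (0.15) and mitosis (0.14) on the higher side, and the integrated stress response (-0.34), antioxidant genes (-0.30), p53 targets (-0.33), histones (-0.50), cholesterol synthesis (-0.39), glycolysis (-0.21) and immediate early genes (-0.74) on the lower side. Their adjusted p ran from 3.78e-06 to 0.0195 and, with an estimated correlation, adjusted p = 0.223 to 0.647.

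Heavy polysomes of HMEC were compared for mRNAs on more than 6 ribosomes in normal cells. SLIT2 rose by 2.70 ± 0.32 (log2, SE, n = 2 against 2), ACTG2, a smooth muscle actin, by 2.67 ± 0.42, TAGLN, transgelin, by 2.24 ± 0.41, MYH9 by 2.19 ± 0.17 and COL16A1 by 2.06 ± 0.37. WNT5A, a secreted signal, rose by 2.23 ± 0.54. The genes that fell were led by PM20D2 at -1.87 ± 0.19, FAM46A at -1.85 ± 0.45, RBM47, an RNA-binding protein, at -1.55 ± 0.25, CCNG1, cyclin G1, at -1.47 ± 0.31, SDCBP at -1.40 ± 0.15 and IBTK at -1.38 ± 0.23. The test called 374 genes higher and 182 lower, and 28 and 8 of those called in total RNA were among them, with 0 in opposite directions. The share of higher genes was 67.3% here, 55.8% with DESeq2 (1073 calls) and 56.8% with the RLE scaling, and no filter on low counts gave 1182 calls. The count was 178 without control replicate 1 (80 higher and 98 lower, the opposite balance), 185 without control replicate 2 and 282 without shEIF4E replicate 1, and a fit of the HMEC libraries alone gave 11.

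Mesenchymal, basal and NF-kB genes led the lists in HMEC heavy polysomes. Of 30 mesenchymal genes, 10 were called higher and 0 lower, or 15 adjusted over the list alone (adjusted p = 2.96e-12, adjusted p = 0.00156 with an estimated correlation). CYR61, a matricellular protein, rose by 1.11 ± 0.15, TNC, tenascin, by 1.54 ± 0.26 and ITGA5, an integrin, by 1.30 ± 0.20. Of 30 basal markers, 5 rose, or 22 adjusted over the list alone (adjusted p = 2.96e-12, adjusted p = 0.382 with an estimated correlation), with the laminin gene LAMA3 up by 1.74 ± 0.28, KRT17 by 1.36 ± 0.33 and EGFR by 0.75 ± 0.14. Basal markers differed between the control cultures as well, with KRT14 at 87.6 and 68.3 CPM in the controls and 150 and 111 CPM with shEIF4E. Of 23 NF-kB genes, 5 rose, or 15 adjusted over the list alone (adjusted p = 8.89e-11, adjusted p = 0.333 with an estimated correlation), with IL6 up by 2.02 ± 0.37, NFKB2 by 1.51 ± 0.29 and RELB by 1.44 ± 0.35. Of 15 stromal markers, 4 rose and 1 fell, or 7 and 1 adjusted over the list alone (adjusted p = 0.000586, adjusted p = 0.0581 with an estimated correlation), with COL1A1 up by 1.90 ± 0.30 and COL6A3 by 1.88 ± 0.38.

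The other 7 lists called in HMEC heavy polysomes were lost with an estimated correlation (adjusted p = 0.395 to 0.933). Interferon response had 2 of 43 genes higher, GBP1 by 1.18 ± 0.29 and OAS3 by 0.74 ± 0.19, or 4 adjusted over the list alone (adjusted p = 0.000389). Mitosis had 4 of 41 higher, or 11 adjusted over the list alone (adjusted p = 0.000427), among them TOP2A, a topoisomerase, KIF4A, a kinesin, by 1.08 ± 0.16 and KIF23, another kinesin, by 0.67 ± 0.15. The integrated stress response had 1 of 37 lower, PSAT1 of serine synthesis, at -0.92 ± 0.23, or 6 adjusted over the list alone (adjusted p = 0.000427). For p53 targets, GADD45A rose by 1.04 ± 0.18 and TNFRSF10B, a death receptor, fell by 0.74 ± 0.14, or 1 and 5 adjusted over the list alone (adjusted p = 0.00523). Antioxidant genes had a median of -0.18 (adjusted p = 0.00106), with 0 of 29 called by edgeR in either count, 7 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom. Cholesterol synthesis had a median of -0.28 (adjusted p = 0.0324), with 0 of 25 called by the 3 tools and 0 at an unadjusted p under 0.05. Histones had a median of -0.48 (adjusted p = 0.00389), although the 1 member called over all genes was higher, with few counts, and 1 higher and 3 lower were called adjusted over the list alone. In the initiation list EIF4E, PDCD4 and MKNK2 fell, PDCD4 at -0.99 ± 0.20 and MKNK2 at -0.81 ± 0.19, and EIF3A was 1 of 2 that rose (adjusted p = 0.197). The 29 literature transcripts had 0 called by edgeR in either count, 4 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom (adjusted p = 0.61).

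**Figure D4:**
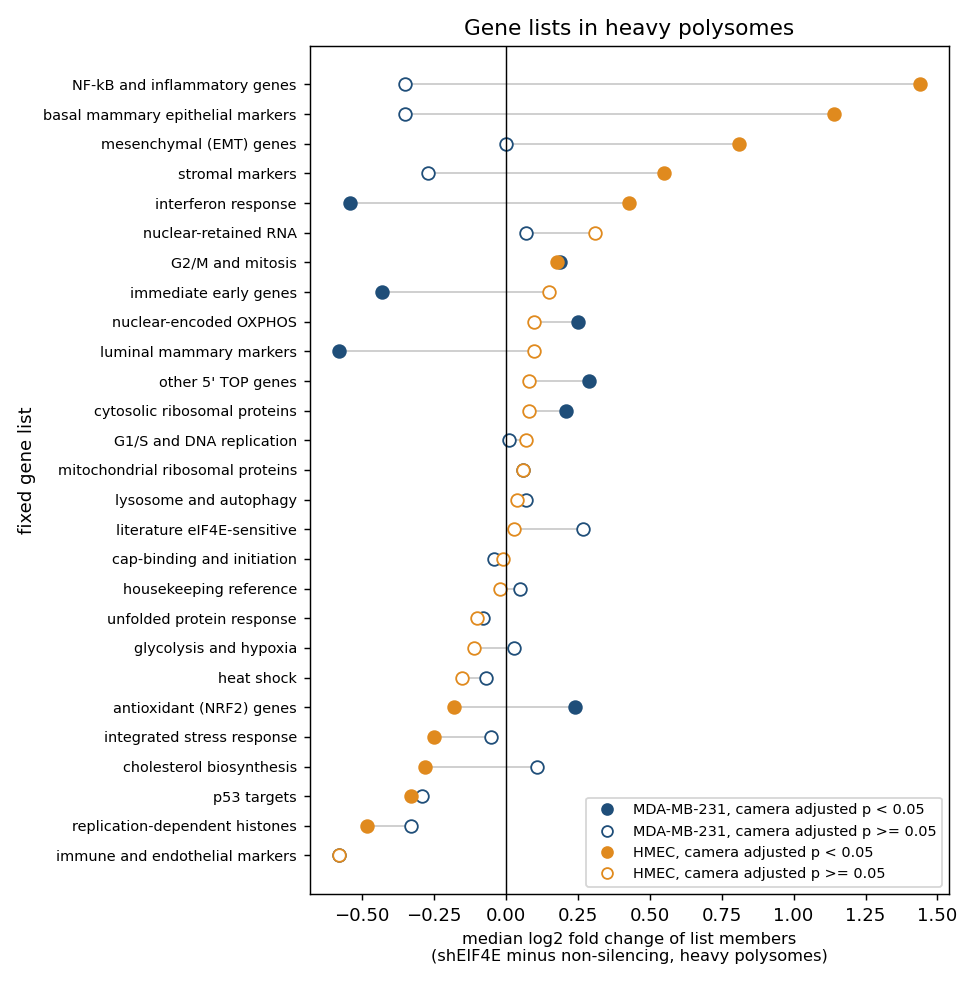
Median log2 fold change (shEIF4E minus control) of each fixed gene list in heavy polysomes, with 1 point per cell line, filled where camera with its preset correlation passed. Basal and NF-kB genes reached 1.14 and 1.44 in HMEC heavy polysomes, and interferon response genes -0.54 in MDA-MB-231.

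In light plus moderate polysomes of HMEC, COL1A1 rose by 2.34 ± 0.31 (log2, SE, n = 2 against 2), WNT5A by 2.21 ± 0.53, KRT5 by 2.18 ± 0.43, LAMC3, a laminin, by 2.07 ± 0.26 and KRT6B by 2.06 ± 0.50. SAMD11 at -1.79 ± 0.31, FAM46A at -1.68 ± 0.44, PM20D2 at -1.55 ± 0.18 and GPX3 at -1.51 ± 0.25 were lower. KRT5 stood at 241 and 120 CPM in the controls and 739 and 891 CPM with shEIF4E. The comparison, for mRNAs on 2 to 6 ribosomes, called 303 genes higher and 190 lower. Of 30 mesenchymal genes 7 rose, or 14 adjusted over the list alone, with TGFBI up by 1.18 ± 0.20 (adjusted p = 1.92e-10, adjusted p = 0.00438 with an estimated correlation). Basal markers had 9 of 30 higher, or 18 adjusted over the list alone, with KRT17 up by 1.97 ± 0.34 and PKP1 by 1.21 ± 0.20 (adjusted p = 2.29e-15, adjusted p = 0.287 with an estimated correlation). NF-kB genes had 3 of 23 higher, or 16 adjusted over the list alone (adjusted p = 6.5e-10, adjusted p = 0.287 with an estimated correlation). The other 10 lists called, lost with an estimated correlation (adjusted p = 0.143 to 0.562), were interferon response (median 0.33), mitosis (0.18), DNA replication (0.13), TOP genes (0.11), luminal (0.14) and stromal markers (0.53) on the higher side, and the integrated stress response (-0.14), p53 targets (-0.32), histones (-0.60) and immune or endothelial markers (-1.10) on the lower side. The count of genes was 154 without shEIF4E replicate 1 and 286 without control replicate 1 (140 higher and 146 lower, the opposite balance), and a fit of the HMEC libraries alone gave 1. With DESeq2 it was 1198, with limma-voom 901 and without a filter on low counts 1154.

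The interaction terms of HMEC asked whether polysome loading, relative to other transcripts, changed beyond abundance in normal cells. EIF4E differed by -0.82 ± 0.31 between heavy polysomes and total RNA (adjusted p 0.917, n = 1 to 2 per group), and no gene passed heavy minus total: 0 by edgeR, with 967 at an unadjusted p under 0.05, 7 by DESeq2 and 0 by limma-voom. For heavy minus light plus moderate, 0 genes passed by edgeR, with 578 at an unadjusted p under 0.05, 8 by DESeq2 and 0 by limma-voom. The 578 lie below a share of 0.05 of the tested genes, so that test was conservative. With each culture as a block, which the design allows because the RNA classes of a culture are paired, the calls were 85 and 19. That block in a fit of HMEC alone, an alternative added after the data were seen, gave 2 and 0, the latter by edgeR with 724 at an unadjusted p under 0.05. Testing without a filter on low counts gave 62 and 2. In heavy minus total, ribosomal proteins lay lower than other genes (median -0.23, adjusted p = 1.27e-12), as did TOP genes (-0.26, adjusted p = 0.000293), cap-binding and initiation genes (-0.17, adjusted p = 0.00698) and mitochondrial ribosomal proteins (-0.14, adjusted p = 0.0145). Immediate early genes (0.85, adjusted p = 0.000457) and stromal markers (0.62, adjusted p = 0.0181) lay higher. No call held, with adjusted p = 0.52 to 0.96 with an estimated correlation, and in these 6 lists 0 single genes were called by the 3 tools. Along the gradient, ribosomal proteins lay higher (median 0.16, adjusted p = 0.0413, adjusted p = 0.955 with an estimated correlation), but not with the RLE scaling (adjusted p = 0.107).

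The difference between the cell lines was tested as the MDA-MB-231 change minus the HMEC change, to ask which responses to EIF4E silencing separate transformed from normal cells. In heavy polysomes 1272 genes differed, 596 of them with a higher and 676 with a lower value in MDA-MB-231, and in total RNA 867 (417 and 450). The balance depended on the scaling: RLE gave 705 higher and 594 lower in heavy polysomes and DESeq2 1049 and 860, and in total RNA DESeq2 gave 725 and 707, as leaving out MDA-MB-231 shEIF4E replicate 2 gave 250 and 237. STMN3 differed by 4.06 ± 0.41 (log2, SE, n = 2 per group), SCARA3 by 3.92 ± 0.32, L1CAM by 3.27 ± 0.46 and LY6E by 3.15 ± 0.29, and SRGN by -4.21 ± 0.23 in heavy polysomes. SRGN stood at 152 ± 28.5 CPM in MDA-MB-231 controls and 10 ± 0.463 CPM with shEIF4E, and at 66.8 ± 1.7 and 81.9 ± 6.55 CPM in HMEC (SD, n = 2 each). EIF4E fell less in MDA-MB-231 heavy polysomes, by 1.32 ± 0.28 (adjusted p 0.00872), while its difference in total RNA was 0.44 ± 0.29 (adjusted p 0.476). For heavy minus total, 0 genes differed by edgeR, with 539 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom, 21 without a filter on low counts and 2 with the cultures as a block. In heavy polysomes, leaving out MDA-MB-231 shEIF4E replicate 1 gave 617 genes, control replicate 1 gave 751 and control replicate 2 gave 703, against 1909 with DESeq2, and the balance turned without MDA-MB-231 shEIF4E replicate 1 or 2, MDA-MB-231 control replicate 1, HMEC shEIF4E replicate 1 or HMEC control replicate 1 (51% to 57.5% higher). In total RNA, leaving out any 1 of the 4 MDA-MB-231 libraries gave 423 to 518 and leaving out HMEC control replicate 2 gave 541 (271 higher and 270 lower), against 1432 with DESeq2 and 1524 without a filter.

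By list, NF-kB genes differed in heavy polysomes with a median of -1.57 and 6 of 23 lower in MDA-MB-231, or 9 adjusted over the list alone (adjusted p = 2.79e-07). Interferon genes had a median of -0.96 and 8 of 43 lower, or 15 adjusted over the list alone (adjusted p = 7.96e-08), SAMD9L by -2.53 ± 0.47. Antioxidant genes had a median of 0.62 and 6 of 29 higher, or 8 adjusted over the list alone (adjusted p = 1.28e-06), TXNRD1 by 1.93 ± 0.30. Basal markers (median -1.50), mesenchymal genes (-0.56), immediate early genes (-0.66), oxidative phosphorylation (0.18) and ribosomal proteins (0.13) differed too, with adjusted p = 0.000157 to 0.00577. With an estimated correlation none of the 8 held (adjusted p = 0.202 to 0.905 with an estimated correlation). Both cell lines shared some changes. Of 128 genes called in heavy polysomes of both, 62 were higher in both and 25 lower in both, where independent lists would share 25 and 11, and 24 and 17 went opposite ways, where independent lists would share 22 and 12. The genes that follow were chosen after their values were seen. THBS1 rose by 1.70 ± 0.35 in MDA-MB-231 and 1.81 ± 0.35 in HMEC, FN1, fibronectin, by 1.39 ± 0.22 and 1.15 ± 0.22, and SPTAN1, a spectrin, by 1.48 ± 0.17 and 1.20 ± 0.16. SDCBP lay at -1.13 ± 0.15 and -1.40 ± 0.15 and PDCD4 at -1.36 ± 0.21 and -0.99 ± 0.20. ITGA5 moved by -1.15 ± 0.20 in MDA-MB-231 and 1.30 ± 0.20 in HMEC, JAG1, a Notch ligand, by -1.34 ± 0.14 and 0.95 ± 0.14, and DUSP5 by -1.35 ± 0.15 and 0.87 ± 0.15.

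**Figure D5:**
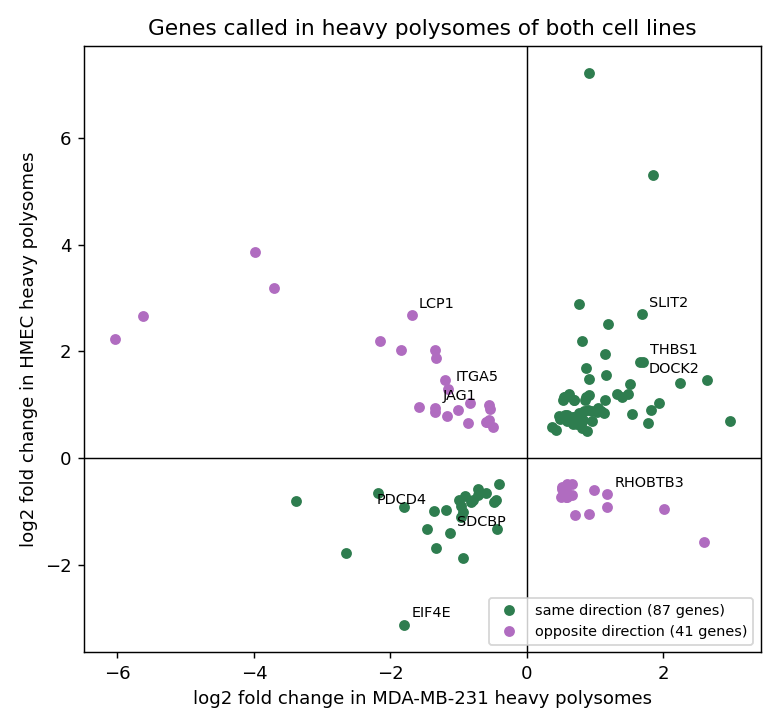
Log2 fold change in heavy polysomes of MDA-MB-231 (horizontal axis) and HMEC (vertical axis) for the 128 genes called in both, 1 point per gene. The 87 genes that moved the same way lie at the lower left and upper right, and 41 lie in the other corners.

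Control cells were compared between heavy and light plus moderate polysomes to see how transcripts lay along the gradient without silencing. Ribosomal proteins lay low in heavy polysomes: 68 of 80 genes were lower and 6 higher in MDA-MB-231 (median -1.38) and 70 lower and 1 higher in HMEC (median -0.99). Genes of oxidative phosphorylation had medians of -1.22 and -0.95. Heat shock genes had medians of 2.33 and 2.12, mitosis 1.22 and 1.24 and DNA replication 1.20 and 1.11. These lists passed camera with its preset correlation, with adjusted p = 2.85e-19 to 0.000103, and were lost with an estimated correlation (adjusted p = 0.084 to 0.42). Mesenchymal genes, with medians of 1.19 and 1.32, held in MDA-MB-231 (adjusted p = 0.0225 with an estimated correlation) and not in HMEC (adjusted p = 0.0679 with an estimated correlation). Of 18853 genes, 4349 were higher and 5858 lower in heavy polysomes of MDA-MB-231 and 4024 higher and 4093 lower in HMEC (n = 2 against 2 each). The median of all genes was -0.42 and -0.23, and in MDA-MB-231 it moved to -0.27 with DESeq2 and -0.30 with the RLE scaling, so the values above are relative to a zero that depends on the scaling.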

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

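The tests of separately derived stable lines, for genes called in both cell lines and for genes called in MDA-MB-231 alone, were chosen only after the result was seen. The fold differences of genes and the medians of lists in this part are differences between the cell lines in their change with shEIF4E (MDA-MB-231 minus HMEC), from an interaction term in the fit of both. By this term 867 genes differed in total RNA and 1272 in heavy polysomes. For EIF4E in heavy polysomes the difference was 1.32 ± 0.28 (adjusted p 0.00872, and 0.000245 to 0.0451 over the alternatives).

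In total RNA the named genes with a higher value in MDA-MB-231 were TP53I11 (5.19), CLU (4.60), SCARA3 (4.36), LY6E (3.80), STMN3 (3.70) and ATOH8 (3.64). Those with a lower value were TNS4 (-8.78), SRGN (-4.87), ANKRD1 (-4.47), LPXN (-4.20), ARHGDIB (-4.19) and IL11 (-4.13). In heavy polysomes they were STMN3 (4.06), COL1A2 (3.95), SCARA3 (3.92), CLU (3.32), L1CAM (3.27) and LY6E (3.15), and TNS4 (-8.72), PHGDH (-5.88), LCP1 (-4.37), ANKRD1 (-4.28) and SRGN (-4.21). Some of these rest on few counts in 1 cell line, and their fold then depends on the prior count. In heavy polysomes TNS4, a focal adhesion gene, stood at 256 ± 15.9 CPM in MDA-MB-231 controls, 0.571 ± 0.0461 CPM with shEIF4E, and 487 ± 185 and 461 ± 179 CPM in HMEC (SD, n = 2 each). PHGDH, the first enzyme of serine synthesis, stood at 5.53 ± 3.50 and 0.063 ± 0.0281 CPM in MDA-MB-231 and 403 ± 46.5 and 291 ± 27.7 CPM in HMEC. ANKRD1 stood at 2450 ± 638 and 498 ± 63.3 CPM in MDA-MB-231 and at 0.269 ± 0.188 and 1.13 ± 0.91 CPM in HMEC.

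Among the fixed lists, camera with its preset correlation separated 4 from other genes in total RNA: antioxidant genes (median 0.68), interferon response (-0.63), NF-kB (-1.59) and basal markers (-1.07), with adjusted p = 3.1e-08 to 0.00072 and, with an estimated correlation, adjusted p = 0.403 to 0.903. In heavy polysomes it separated ribosomal proteins (0.13), oxidative phosphorylation (0.18), antioxidant genes (0.62), interferon response (-0.96), NF-kB (-1.57), mesenchymal genes (-0.56), basal markers (-1.50) and immediate early genes (-0.66), none with an estimated correlation (adjusted p = 0.202 to 0.905). For heavy minus total it separated ribosomal proteins (0.24), TOP genes (0.25), mitochondrial ribosomal proteins (0.09), oxidative phosphorylation (0.09), DNA replication (-0.16), glycolysis (-0.29) and immediate early genes (-0.87). Their adjusted p ran from 8e-08 to 0.0441, and with an estimated correlation it was adjusted p = 0.818 for each.

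Most changes called in heavy polysomes of MDA-MB-231 were not called in HMEC. Too little power in HMEC stays open. The HMEC changes of the 2360 genes called in MDA-MB-231 followed theirs with a Spearman correlation of 0.05, or 0.1 across the 1265 of them expressed in HMEC, where genes are not independent replicates. However, the heavy change correlated between the cultures numbered 1 and 2 at 0.3 in HMEC, against 0.84 in MDA-MB-231. Such low agreement within HMEC lowers any correlation with MDA-MB-231, so the low value cannot decide this. For the 128 genes called in both, differences between separately derived stable lines as a source cannot be settled. Of these genes, 87 (68%, 95% interval 59.1 to 75.9% if genes were independent) moved the same way. In 30 pairs of replicate differences of unrelated cultures, the share had a median of 53.2% and was at most 62.7%. Those replicate differences lie within a stable line and hold none between lines, so they cannot stand for this explanation. For the 2232 genes called in MDA-MB-231 and not in HMEC, an effect of eIF4E silencing and a difference between stable lines cannot be told apart, because each shRNA was represented by 1 line per cell line. A difference between transformed and normal cells, which the design names, stays open as well.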

How the results depend on the processing

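The separate fit with a block for the culture, the correlations of group means with coding length and the coding lengths of HMEC calls without each control library were chosen only after the data were seen, and the other alternatives were fixed before the data were examined. Over all alternatives, 0 genes called both in the main fit and in the alternative had opposite signs. Genes that lost their call were checked for sign only among the gene values named below, of which 0 reversed. EIF4E kept its direction and its side of the threshold in each RNA class of each cell line under the alternatives run, except that in HMEC total RNA a fit of HMEC alone gave -2.33 (adjusted p 0.0612). For heavy minus total it passed under none of them, at -0.24 to 0.27 in MDA-MB-231 and -0.99 to -0.70 in HMEC. Of 234 gene values named, 232 calls held with DESeq2, 227 with limma-voom, 231 with RLE scaling, 234 without a filter on low counts and 127 with each library left out in turn. In separate fits, 123 of 123 held in MDA-MB-231 and 5 of 86 in HMEC.

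The count of called genes moved with several choices. In separate fits, MDA-MB-231 had 5097 genes in total RNA, 5096 in heavy and 5979 in light plus moderate polysomes, and HMEC had 0, 11 and 1, the 11 all called in the joint fit too. The coefficient of variation was 0.116 in MDA-MB-231 alone, 0.249 in HMEC alone and 0.183 jointly, and the separate fits differed from the joint fit also in scaling, genes tested and residual degrees of freedom. DESeq2 gave 411 genes in HMEC total RNA, 1073 in heavy and 1198 in light plus moderate polysomes, 7 for heavy minus total and 8 for heavy minus light plus moderate, and 1432 and 1909 for the difference between cell lines in total RNA and heavy polysomes. Limma-voom gave 901 in HMEC light plus moderate polysomes. Without a filter on low counts, HMEC had 866 genes in total RNA, 1182 in heavy and 1154 in light plus moderate polysomes, 62 for heavy minus total and 2 for heavy minus light plus moderate, and the cell lines differed in 1524 in total RNA and 21 for heavy minus total. The cause was not tested for these. With the contradicting titles read by their words, HMEC gave 62 genes in light and 176 in moderate polysomes alone. Those titles are of MDA-MB-231, so HMEC moved only through what the joint fit shares between cell lines: read by their codes, it gave 394 and 627.

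Leaving out each library in turn, which leaves a group with 1 library assumed to vary like the others, gave 1117 to 1211 genes in MDA-MB-231 total RNA, 1153 to 1454 in heavy and 1377 to 1777 in light plus moderate polysomes. In HMEC it gave 1 to 11, 178 to 717 and 154 to 608, and for the difference between cell lines 423 to 782 in total RNA and 617 to 1637 in heavy polysomes. For control cells along the gradient it gave 8098 to 8763 and 6007 to 8052. The interaction terms stayed at 0 by edgeR's test, with the counts at an unadjusted p given above for the full data.

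The block for the replicate number within a cell line gave 3860 genes in MDA-MB-231 total RNA and 3636 in heavy polysomes, 466, 1612 and 1743 in HMEC total RNA, heavy and light plus moderate polysomes, and 1638 and 2465 for the difference between cell lines in total RNA and heavy polysomes. It kept 234 of the 234 named calls. Whether equal numbers mean cultures handled together is not stated. Deviations from the group mean correlated between shRNAs of equal number at 0.59 (total), 0.39 (heavy) and 0.66 (light plus moderate) in MDA-MB-231 and at 0.06 (heavy) and 0.33 (light plus moderate) in HMEC, where the column codes of replicate 2 differ between shRNAs. The block for the culture gave 85 genes for HMEC heavy minus total, 19 for HMEC heavy minus light plus moderate and 2 for the cell line difference of heavy minus total, and changed no other call of an interaction term. With a separate fit added, HMEC heavy minus total had 2, and HMEC heavy minus light plus moderate had 0 by edgeR, with 724 at an unadjusted p under 0.05.

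For the gene lists, an estimated correlation left 0 of 7 in MDA-MB-231 total RNA, 0 of 8 in heavy, 0 of 7 in light plus moderate polysomes and 0 of 6 for heavy minus light plus moderate. It left 1 of 14 in HMEC total RNA, 1 of 11 in heavy and 1 of 13 in light plus moderate polysomes (mesenchymal genes in each), 0 of 6 for heavy minus total and 0 of 1 for heavy minus light plus moderate. For the cell line difference it left 0 of 4, 0 of 8 and 0 of 7. With the replicate block, 2 lists passed for MDA-MB-231 heavy minus total (DNA replication and immediate early genes, adjusted p = 0.0204 each), 0 for HMEC heavy minus light plus moderate and 11 for the cell line difference of heavy minus total. These are at the preset correlation. An estimated correlation was not combined with the block, and without it 0 lists passed for MDA-MB-231 heavy minus total.

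With 12908527 to 33249118 counts per library and 1 or 2 cultures per group, changes of 1.5-fold were seldom called in simulated data. At most 11.9% of them were, with a spread shared by both cell lines and with changed genes drawn only from those above a floor on mean level. Depth was not varied, and counts of replicates differed by more than counting error, with a chi-square of 13.3 to 100.4 per degree of freedom. For heavy minus total in MDA-MB-231, 19.4% of changes of 2-fold were called.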

Other observations

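The test of eIF4E silencing acting alike in both cell lines, the correlations of group means with coding length, those of total RNA and the coding lengths without each control library were chosen only after the result was seen, and so were the genes named in this part. Several genes of stress responses changed in heavy polysomes of MDA-MB-231 although their lists did not pass. In the integrated stress response, with 2 of 37 genes higher and 4 lower (camera adjusted p = 0.472), SLC7A11, a cystine transporter, rose by 1.47 ± 0.32 (log2, SE, n = 2 against 2) and the cytokine gene GDF15 fell by 1.97 ± 0.42. CDKN1A, a cyclin-dependent kinase inhibitor and p53 target, was lower, at -1.50 ± 0.44. In the unfolded protein response, with 2 of 24 higher and 3 lower (adjusted p = 0.842), CREB3L2 rose by 0.99 ± 0.16 and the chaperone gene HSP90B1 by 0.63 ± 0.16, and MANF fell by 0.76 ± 0.20. In HMEC heavy polysomes, DNA replication had 4 of 47 genes higher and 2 lower, or 10 and 2 adjusted over the list alone (adjusted p = 0.136). The polymerase genes POLE and POLA1 rose by 1.19 ± 0.12 and 0.89 ± 0.17, and GINS1 fell by 0.90 ± 0.15. In HMEC light plus moderate polysomes, 3 of 34 genes of glycolysis rose, PFKP by 1.12 ± 0.22, HK1 by 1.06 ± 0.20 and PKM by 0.74 ± 0.16 (adjusted p = 0.573).

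Among genes called in heavy polysomes of both cell lines, SLIT2 rose by 1.68 ± 0.31 in MDA-MB-231 and 2.70 ± 0.32 in HMEC, and the collagen gene COL6A2 by 1.66 ± 0.34 and 1.80 ± 0.34. MITF, a transcription factor, was lower in both, at -1.80 ± 0.19 and -0.92 ± 0.23, as were the arrestin gene ARRB1, at -1.19 ± 0.17 and -0.98 ± 0.17, and PGM3, a phosphoglucomutase, at -0.97 ± 0.17 and -1.11 ± 0.17. Opposite directions were found for COL6A3, at -1.33 ± 0.32 and 1.88 ± 0.38, and RHOBTB3, at 1.18 ± 0.15 and -0.67 ± 0.15. In light plus moderate polysomes, 198 genes were called in both cell lines and 159 of them (80.3%, 95% interval 74.1 to 85.6% if genes were independent) moved the same way. This share was not set against replicate differences. In control cells, glycolysis lay high in heavy polysomes, with medians of 1.15 in MDA-MB-231 and 0.85 in HMEC, as did the unfolded protein response (0.94 and 0.81) and lysosomal genes (1.26 and 0.95), while mitochondrial ribosomal proteins (-0.76 and -0.73) and histones (-1.50 and -1.11) lay low. Each of these passed camera with its preset correlation and was lost with an estimated correlation, with adjusted p = 0.084 to 0.493.

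In MDA-MB-231, the change of heavy minus light plus moderate polysomes with shEIF4E fell with coding length, with a Spearman correlation of -0.52 for the group means. The correlation was 0.25 for the change in light plus moderate and -0.04 for that in heavy polysomes, and heavy minus total, which uses no light plus moderate library, fell with coding length too (-0.34, and -0.35 as a partial correlation). Gene by gene, the change of heavy minus total did not reproduce between the cultures numbered 1 and 2 (correlation -0.01). Since each class is scaled by itself, this does not show that long mRNAs left heavy polysomes. GC content and UTR lengths of transcripts are argued against, since the partial Spearman correlation with coding length was -0.41 and -0.55 for the cultures numbered alike and -0.53 for the group means. A boundary between fractions placed differently between gradients stays open: the slope on coding length differed between shRNAs by 0.84 of the largest difference between cultures of the same line and shRNA, found in HMEC shEIF4E (0.703 and 0.587), although within MDA-MB-231 the difference between shRNAs (0.605 and 0.653 with shEIF4E against 0.704 and 0.75 in controls, -0.098 between means) exceeded the largest between cultures of the same shRNA (0.048). Whether eIF4E silencing acted alike in both cell lines cannot be told apart from other sources, because the HMEC cultures numbered alike gave 0.12 and -0.13. Light and moderate counts weigh in their sum by sequencing depth, which differed between libraries. For replicate 1, light and moderate libraries held 24669875 and 27332400 counts with shEIF4E, against 25696002 and 24214577 in the control. For replicate 2 they held 23143896 and 29171210 against 25991005 and 29245954, with the contradicting titles read by code. A part from this weighting was not tested and stays open, although heavy minus total does not use the sum. An effect in MDA-MB-231 cells stays open too.

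Genes called higher in HMEC heavy polysomes had long coding sequences, with a median of 3096 nt against 1428 nt for all tested genes. A single gradient is argued against as the whole source of these calls, since the ratio of these medians was 2.17 with all 4 heavy libraries, 1.95 without shEIF4E replicate 1, 2.26 without shEIF4E replicate 2, 2.05 without control replicate 1 (80 genes higher) and 2.66 without control replicate 2. Across 7867 genes, however, the heavy change followed coding length with a Spearman correlation of 0.40 for the cultures numbered 1 and -0.08 for those numbered 2, so a part from the gradients numbered 1 stays open. A part from higher abundance of the same transcripts in total RNA cannot be told apart, because HMEC shEIF4E has 1 total RNA library, from the culture numbered 1. The median change of these 374 genes in total RNA was 0.50, or 0.55 of the 0.92 in heavy polysomes. Against abundance, the total RNA change did not rise with coding length (-0.05 for the group means and -0.02 for the cultures numbered 1), and heavy minus total did (0.32 and 0.54). In MDA-MB-231 the ratio was 1.00 for higher and 1.05 for lower genes in heavy polysomes, the difference between cell lines was not tested, and a change in translation of long mRNAs stays open.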
